A study of Bacillus subtilis with 4 samples.

How the data were processed

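Total RNA of 4 Bacillus subtilis cultures was amplified, labelled and hybridised to 4 Agilent two-colour arrays, per the labels. Cy3 marks the 20 min sample and Cy5 the mixture of 0 min samples on every array, so dyes were not swapped. Groups came from each sample's own labels, with 2 untreated cultures and 2 cultures with 4 mM ferric iron. The series' design text names 1 of the untreated arrays, that of replicate 2, under both conditions. The description, source and growth condition of every sample, and the replicate pairs given in the same text, put it among the untreated. Replicates are independent cultures, per the labels. All 4 arrays lay on 1 slide and were recorded in 1 scan, so neither gives a batch. Replicate 1 and replicate 2 lay in different rows of the slide. Both untreated arrays lay in column 2 and both iron arrays in column 3, so condition and slide column cannot be told apart. In Cy5, where all arrays held the mixture, iron minus untreated had an SD over identifiers of 0.082 in replicate 1 and 0.075 in replicate 2. These 2 differences correlated at 0.287.

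The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 10.7.3.1, per the file headers. Each holds 15744 spots, of which 15208 are gene spots. Per the file headers, the software gave each spot the median intensity of its pixels and of its local background, a background-subtracted intensity and a processed intensity after dye normalization, together with flags. The deposited log10 ratio is that of processed Cy5 over processed Cy3 signal, as computed by the same software per the file headers. The deposited series table holds log2 values per probe. Set against the scanner files, these matched log2 of processed Cy3 over processed Cy5 within 0.001 for 100% of the 12312 probes with a single spot, so their scale and direction are known; they are not centred, with medians of 0.03, 0.04, -0.02 and 0.04. The genome build and annotation behind the array are not given in the sources used here.

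The median spot intensity was background-corrected with normexp and an offset of 50, normalized within each array by loess with control and outlier spots at weight 0, and turned to log2 of sample over reference, with R 4.3.3 and limma 3.58.1. Normexp had been planned on all spots. That model was inflated on all 4 arrays by spots that carried the scanner software's flag for an uneven local background, 9 to 83 per array. The fitted Cy3 background SD was 51.2 on untreated replicate 1, 16.6 on untreated replicate 2, 8.53 on iron replicate 1 and 547 on iron replicate 2, where 83 spots were flagged and the local background reached 42662 units against a median of 31. With such spots set aside it was 1.03 to 1.13 on the 4 arrays. The values reported set these spots aside on all arrays. This departs from the plan and was chosen after seeing the data, including the counts under both versions, so the values with the model fitted on all spots stand beside the results they move. An offset of 50 lies above the median net signal, so fold changes of dim genes are understated.

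Spots of a probe were averaged, then the probes of an identifier. A probe was kept where it was well above background in Cy3 on both arrays of a condition or in Cy5 on all 4 arrays, which left 9460 of 12420 probes and 3555 of 4212 identifiers. Saturated spots would have been kept; 0 gene spots were saturated. All 4 arrays entered a single limma fit, with the contrast of iron minus untreated and each group mean against 0, Benjamini-Hochberg adjustment and a threshold of 0.05. A count without a test took identifiers at least 2-fold apart in all 4 pairings. A probe not well above background on every array of a group has only a bound there: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

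The rule for single genes, fixed before the data were examined, took the largest changes among called genes with no overlap between groups or, where too few were called, the largest changes without overlap, said to fail the test; genes below background in a whole group were left to bounds. Since names are missing it was held to 2 identifiers in each direction. Of the 4104 identifiers of one series 0 were found in the gene table used, assembly ASM904v1, and of the 108 of the other 0. The 39 gene lists fixed beforehand, among them the Fur and PerR regulons, general stress, sporulation and competence, had 0 lists with a member found by name, so no gene list was tested, and the single genes fixed by name are not reported.

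The procedure was tested on simulated data for iron against untreated at 20 min over 3555 genes, with 50 genes changed at each size. With a gene-to-gene spread drawn from the fit, 1 gene was called at 2-fold, 12 at 4-fold, 30 at 16-fold and 25 at 32-fold, with 2 false calls. The median fitted size was 0.49, 0.95, 1.99 and 2.64 on the log2 scale for true sizes of 1, 2, 4 and 5. With a small technical spread, 42, 47, 49 and 49 were called, with 11 false calls. The simulated spread was drawn independently for each gene and array. It held neither the shift shared by same-numbered arrays nor the correlation of neighbouring identifiers described below. So these counts do not give the power or the false calls to expect in the real data. Alternatives covered background correction, offset, normalization within and between arrays, the scanner software's log ratio, the deposited log2 values, the filter, the brightest probe, the replicate number as a block, each array left out, a trended robust prior and the Cy3 channel alone.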

Results

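Transcript levels of Bacillus subtilis, a Gram-positive soil bacterium, were measured on 4 two-colour oligonucleotide arrays 20 min after cultures in rich LB medium either received 4 mM ferric iron or were left untreated. Each condition had 2 independent cultures with 1 array each. On every array the Cy3 channel held the RNA of a culture at 20 min, and the Cy5 channel held a common reference, a mixture of RNA from the cultures at 0 min. The arrays carried 4212 gene identifiers, of which 4104 had 3 probes each. In Cy3, the share of gene spots well above background ran from 71.0% to 80.3% across the 4 arrays, and in Cy5 from 65.2% to 72.2%. The median background-subtracted signal of a gene spot was 25.1 to 32.6 units in Cy3 and 22.8 to 25.4 in Cy5, so that much of the transcriptome was measured near the lower end of the scale. The filter on dim probes kept 3555 identifiers, and all values below are log2 ratios of the 20 min sample over the 0 min mixture. The number of arrays limits the precision of every value. The files do not pair the identifiers with gene names, so the genes are given by identifier, at most 2 in each direction, and without a function.

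The main comparison asked which transcripts differed between iron-treated and untreated cultures at 20 min. The largest difference was a block of 4 consecutively numbered identifiers that were 24.4-fold to 33-fold lower in the iron cultures. In it, BG13852 stood at -0.61 ± 0.57 (SD, n = 2) in untreated and at -5.66 ± 0.16 (SD, n = 2) in iron cultures, a log2 fold change of -5.05 with an SE of 0.35. For BG13851 the means were -0.66 ± 0.64 (SD, n = 2) and -5.68 ± 0.35 (SD, n = 2), a log2 fold change of -5.03 with an SE of 0.41. Both were lower in each iron culture than in each untreated culture. In the other direction, BG14105 was at 0.16 ± 0.18 (SD, n = 2) in untreated and 3.21 ± 1.5 (SD, n = 2) in iron cultures, a log2 fold change of 3.06 with an SE of 0.81, and its iron arrays read 4.27 and 2.15. BG13916 had a log2 fold change of 2.69 with an SE of 1.03, from 0.27 ± 1.03 (SD, n = 2) to 2.95 ± 1.63 (SD, n = 2). The size of both moved with single arrays: without iron replicate 1 the log2 fold change was 2.00 for BG14105 and 1.53 for BG13916, and without iron replicate 2 it was 4.12 and 3.84. Without untreated replicate 1 that of BG13916 was 3.41, and without untreated replicate 2 it was 1.96. For BG13916, replicate 1 read above replicate 2 in both conditions, at 0.99 and -0.46 in untreated and 4.11 and 1.80 in iron cultures. Leaving out 1 array therefore also moves the balance of replicate numbers. With the replicate number as a block, the log2 fold changes stayed the same. Their SEs were then 0.22 for BG13852, 0.19 for BG13851, 0.28 for BG13916 and 0.53 for BG14105. The limma adjusted p was then 0.0884 for BG13852 and BG13851 and 0.296 for BG14105 and BG13916. The labels do not give the replicate number as a pairing.

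None of these 4 identifiers passed the test across all genes. With limma, the Benjamini-Hochberg adjusted p was 0.433 for BG13852 and for BG13851, 0.910 for BG14105 and 0.940 for BG13916. All 12 probes of the 4 consecutive identifiers were well above background in both dyes on all 4 arrays, and each probe gave a log2 difference between -5.32 and -4.54. The 3 probes of BG14105 gave 2.33 to 3.45, and those of BG13916 gave 2.61 to 2.77. With the normexp background model fitted on all spots, as it had been fixed before the data were examined, the log2 fold change of BG13852 was -4.30 with an SE of 0.74, that of BG13851 -4.15 with an SE of 0.93, that of BG14105 2.33 with an SE of 1.37 and that of BG13916 2.13 with an SE of 1.41, all with a limma adjusted p of 0.970. With the log ratio of the scanner software, BG14105 was at 4.31 with an SE of 0.87 and BG13851 at -5.73 with an SE of 0.58, with limma adjusted p of 0.294 and 0.0873.

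**Figure D1:**
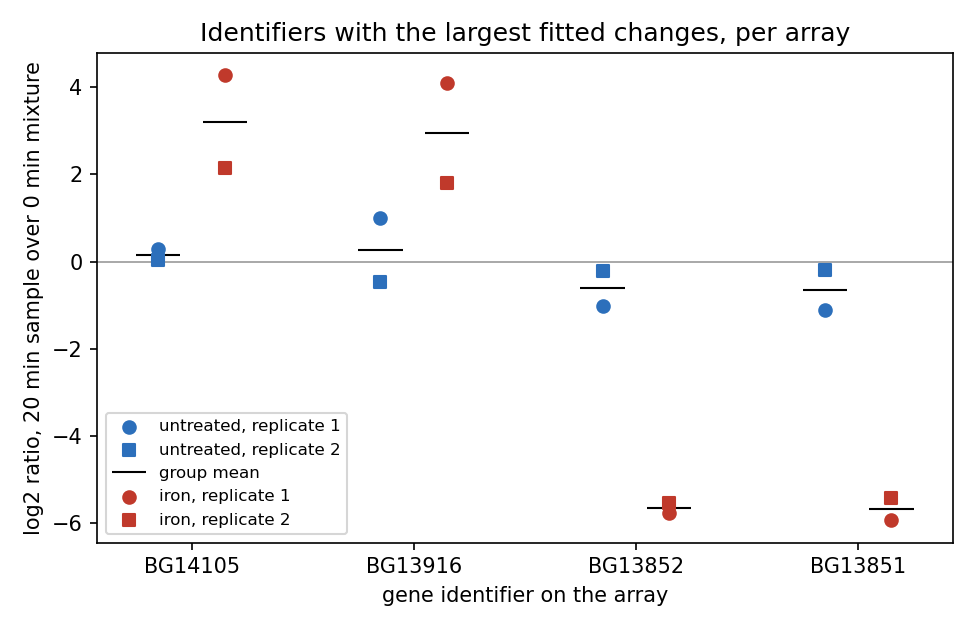
Each point is the log2 ratio of the 20 min sample over the 0 min mixture on 1 array for the identifiers BG14105, BG13916, BG13852 and BG13851, with blue for untreated and red for iron cultures, circles for replicate 1, squares for replicate 2 and a black bar for the mean of the 2 arrays. For BG13852 the iron arrays read -5.77 and -5.54, below the untreated arrays at -1.01 and -0.20.

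Across all 3555 identifiers, limma called 0 at an adjusted p under 0.05. For 172 the unadjusted p was under 0.05, 83 of them higher and 89 lower in iron. Chance would give 178 for exchangeable arrays. Here the same count was 487 for the arrays grouped by replicate number. For iron replicate 1 and untreated replicate 2 against the others it was 29. With the replicate number as a block it was 424, though the labels do not give that number as a pairing. So a count near 178 does not speak against an effect of iron. These 172 are 4.84% of the identifiers tested. The number was 80 with the normexp model fitted on all spots, with 0 called. Leaving out 1 array leaves 1 in a group, so no such number is given for those fits. By size alone, 24 identifiers were at least 2-fold apart in all 4 pairings of an iron with an untreated array, 6 of them higher and 18 lower in iron. At 4-fold, 0 were higher and 5 lower, and at 8-fold the 4 consecutive identifiers were the whole set, all lower. Of the 24 identifiers, 8 lay in 3 runs of consecutive numbers. The 2 iron arrays lay on 1 side of both untreated arrays for 1227 identifiers, 34.5% of those tested, with 696 higher and 531 lower in iron. Chance gives 33.3% for 2 arrays against 2 only where the arrays are exchangeable. The groupings above gave unlike counts, so this share does not show whether iron had an effect.

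The count of 24 and its split by direction moved with the processing and with the arrays. It was 7, with 0 higher and 7 lower, with the normexp model fitted on all spots, 53 with a normexp offset of 16, of which 15 were higher and 38 lower, 38 with median centring, of which 9 were higher and 29 lower, and 136, of which 49 were higher and 87 lower, with the log ratio of the scanner software. Scale normalization between arrays gave 18, with 7 higher and 11 lower. With 1 array left out, which leaves 2 pairings, the larger part was higher in iron in 3 of the 4 cases. Without untreated replicate 1 the count was 138, with 72 higher and 66 lower, without iron replicate 1 it was 103, with 67 higher and 36 lower, and without iron replicate 2 it was 237, with 147 higher and 90 lower. Without untreated replicate 2 it was 90, with 11 higher and 79 lower.

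**Figure D2:**
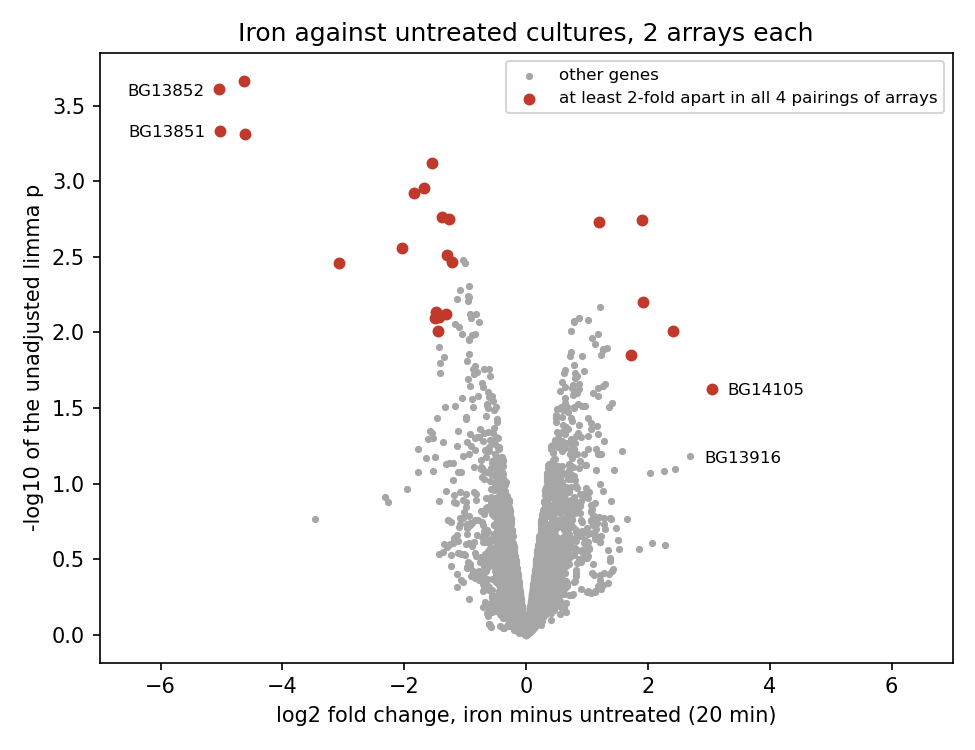
Each point is 1 of the 3555 identifiers, placed by its log2 fold change of iron over untreated cultures at 20 min on the x axis and by the -log10 of its unadjusted limma p on the y axis, with red for the 24 identifiers at least 2-fold apart in all 4 pairings of arrays and grey for the others. The 4 consecutive identifiers lie at the far left between -5.05 and -4.61, and BG14105 is the red point farthest to the right at 3.06.

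Some transcripts were well above background in only 1 condition and have bounds in place of folds. For 153 identifiers no probe was well above background in Cy3 on either iron array while at least 1 probe was on an untreated array, and 35 of these had a probe well above background on both untreated arrays. For 7 of the 153 the untreated level in the Cy3 channel was at least 2-fold above the iron level, with a highest bound of at least 3.91-fold. The fit of the ratios to the mixture, a different scale from that of the bound, put that identifier 3.60-fold lower in iron, with a limma adjusted p of 0.599. Of the 8 bounds of 2-fold or more in either direction, 7 have a fitted fold, and in all 7 it lay below the bound. So these values are lower limits in the Cy3 channel only, not for the fitted folds. Of the 24 identifiers at least 2-fold apart, 3 were among these 153. In the other direction, 90 identifiers had no probe well above background on either untreated array, 18 of them with a probe well above background on both iron arrays, and 1 had a bound of at least 2.16-fold. A further 329 identifiers were not well above background in Cy3 in either condition and have no bound here. The bounds come from the Cy3 channel after loess and Aquantile normalization. Both conditions were read in this dye and no dyes were swapped, so a dye bias that differs between arrays stays in them.

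**Figure D3:**
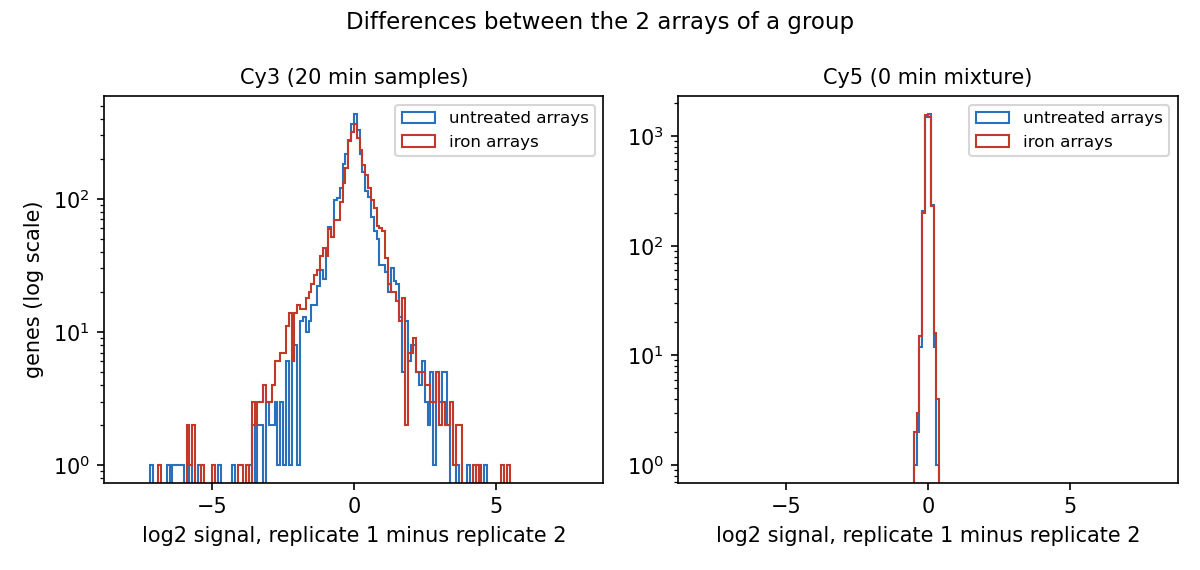
Histograms of the log2 signal of replicate 1 minus replicate 2 for 3555 identifiers, in bins of equal width with the number of genes on a log scale, for the Cy3 channel with the 20 min samples on the left and the Cy5 channel with the 0 min mixture on the right, blue for the untreated and red for the iron arrays. The Cy3 differences have an SD of 0.81 in untreated and 0.91 in iron arrays, and the Cy5 differences 0.07 in both.

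The log2 ratios of the 2 untreated arrays correlated across genes with a Pearson r of 0.263 and those of the 2 iron arrays with 0.360, where genes are not independent replicates. For an iron and an untreated array of the same replicate number, r was 0.579 and 0.636. For those of different numbers it was 0.315 and 0.0757. Replicate 1 minus replicate 2 had an SD over genes of 0.71 in the untreated and 0.83 in the iron cultures on the log2 ratio scale. An iron array minus an untreated array had an SD of 0.62 and 0.58 within the same replicate number, and 0.71 and 0.97 across numbers. So arrays of different conditions with the same number were more alike than the arrays of either condition. The 3 probes of an identifier gave nearly the same difference between iron and untreated, with an intraclass correlation of 0.927 over 2640 identifiers with 3 probes.

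A further comparison set the untreated cultures at 20 min against the 0 min mixture, that is, what changed during 20 min of growth without added iron. Here 60 identifiers were at least 2-fold lower and 9 at least 2-fold higher than the mixture on both untreated arrays. BG13852 was at -0.61 with an SE of 0.24 and BG14105 at 0.16 with an SE of 0.57, with limma adjusted p of 0.487 and 0.954. Limma called 0 of 3555 identifiers, with a smallest adjusted p of 0.250, and 423 had an unadjusted p under 0.05, 99 of them higher and 324 lower at 20 min. With the normexp model fitted on all spots that number was 313, with 0 called. Leaving out an untreated array leaves 1 in that group, so the p would rest on the spread of the iron arrays alone. No count is given for those fits. The mixture is a single sample whose own spread is left out, and a dye bias does not cancel in this ratio.

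The iron cultures at 20 min were set against the same mixture. On both iron arrays, 105 identifiers were at least 2-fold lower and 29 at least 2-fold higher than at 0 min. BG13852 was at -5.66 with an SE of 0.24 and BG13851 at -5.68 with an SE of 0.29, each lower on 2 of 2 arrays and each with a limma adjusted p of 0.0742. BG14105 was at 3.21 with an SE of 0.57 and an adjusted p of 0.129, and BG13916 at 2.95 with an SE of 0.73 and an adjusted p of 0.178, both higher on 2 of 2 arrays. Limma called 0 identifiers, and 657 had an unadjusted p under 0.05, 260 higher and 397 lower at 20 min, against 155 with the normexp model fitted on all spots. The log ratio of the scanner software gave 46 calls, 7 higher and 39 lower, the deposited series values 47, a normexp offset of 16 gave 6, the strict filter 4 and the brightest probe per gene 7. Whether the 2 conditions differ in their change from 0 min is the comparison of iron with untreated cultures above, where the mixture cancels.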

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

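Signals from control probes, which no comparison above uses, were set against the negative controls of each array, and a probe was listed where its median net signal exceeded the negative control mean by 3 SD on all 4 arrays. Of the spike-in probes named E1A, 10 of 10 did so in Cy5, and 10 in Cy3. Their log2 ratios ran from -3.0 to 2.04. Their mean over probes lay 0.30 below their own average on iron replicate 1 and 0.30 above it on iron replicate 2. Relative to the same average it lay at 0.09 on untreated replicate 1 and at -0.09 on untreated replicate 2. These shifts of opposite sign cancel in the mean difference of iron and untreated arrays, which was -0.0036 on the log2 scale. Of the probes named DCP, 17 of 18 exceeded the level in Cy5. Of the probes named ETG, 5 of 13 did so in Cy5 and 3 in Cy3. The probe ETG09_35454 read 46.3 to 59.6 units in Cy5 and 7.72 to 16.8 in Cy3. What the DCP and ETG probes target is not given in the sources used here, and no explanation was tested.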

How the results depend on the processing

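The normexp model on all spots was put beside the others after seeing the data; the other alternatives were planned. Iron against untreated gave 0 calls under all 17 alternatives. With 1 array left out or the replicate block, the spread rests on fewer values, so 0 calls there add little. Where all 4 arrays entered the fit, the smallest limma adjusted p ran from 0.0847 to 0.970. In those fits 80 to 424 identifiers had an unadjusted p under 0.05. Untreated against the mixture gave 0 under all 15, with 313 to 505 at an unadjusted p under 0.05 where all 4 arrays entered the fit. The 4 identifiers named kept their direction under all 17. With 1 array left out this was fixed in advance, since they were picked without overlap between groups. The replicate block, the trended robust prior and both changes of the filter leave their log2 fold changes as they are, so these do not test the direction. Iron against the mixture gave 6 calls with an offset of 16, 46 with the scanner software's log ratio, 47 with the deposited log2 values, 4 with only probes above background in both dyes on all arrays and 7 with the brightest probe, and 0 under 10 others; the cause was not tested. The 24 identifiers at least 2-fold apart became 53 with an offset of 16, 38 with median centring, 136 with the scanner software's log ratio, 137 with the deposited log2 values and 7 with normexp on all spots; 6 alternatives stayed within 1.5 times. Without 1 array the count ran from 90 to 237, as only 2 pairings are then required. With the replicate block, 0 genes were called and 424 had an unadjusted p under 0.05; the 2 same-numbered pairs alone gave 61 at least 2-fold apart, 36 higher and 25 lower. Replicate 1 minus replicate 2 in untreated and in iron cultures correlated across genes at 0.617, iron minus untreated in replicate 1 and in replicate 2 at 0.363, and the log2 ratios of same-numbered arrays at 0.579 and 0.636, with an SD of their difference of 0.62 and 0.58, but the labels give no shared day and there are only 2 pairs, so the number was not taken as a pairing. The planned tests of gene lists were not run, since no identifier could be matched to a name. Low signal over background limits dim genes, whose ratios move most with the offset.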

Other observations

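Of the tests below, those of pair distance and of runs under other groupings were set out before their result was seen; the others were chosen after. Neighbouring identifiers moved together: over 3059 pairs with consecutive numbers, the log2 differences of iron and untreated cultures correlated across genes with a Pearson r of 0.499 and a Spearman rho of 0.459, although genes are not independent replicates. At a distance of 2 numbers r was 0.286, at 5 it was 0.051, and at 100 it was 0.013. The correlation does not rest on the large changes alone, as r was 0.428 over the 2755 pairs in which both members differed by under 2-fold. Chance is argued against by 10000 shuffles of the numbers, which reached at most 0.0667. Neighbouring spots on the array are argued against by the pairs with spots farther apart than the median pair, where r was 0.513. A candidate explanation is that consecutive numbers often mark genes of 1 operon; without gene positions for these identifiers it was not tested.

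The identifiers starting Bsu, with 26 or 27 spots for their single probe, are given apart: 71 of them were tested, 0 reached a fitted 2-fold difference between iron and untreated cultures, 2 had an unadjusted limma p under 0.05, and the median size was 0.17 on the log2 scale.

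The 4 consecutive identifiers that were lowest in iron, BG13851 and BG13852 among them, were examined further. A defect of single spots is argued against by the probe closest to 0 among their 12, at -4.54. A difference between cultures unrelated to iron remains a candidate explanation, but the test set for it cannot decide. It required a run of 4 or more consecutive numbers at least 8-fold apart in another grouping, and that was found. With both replicate 2 arrays against both replicate 1 arrays, 13 identifiers were at least 8-fold apart, with a longest run of 6 consecutive numbers. That run moved alike in both conditions, so it cancels in iron minus untreated. It shows that blocks of this size can differ between cultures, but not that such a difference gave the 4 identifiers lower in both iron cultures. The grouping that crosses conditions and replicate numbers gave 0 at least 8-fold apart, with a longest run of 0. An effect of iron stays open as well, and the 3 ways of splitting 4 arrays are too few to weigh chance.

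The spread between the 2 cultures of a condition lay in the Cy3 samples. Hybridisation or slide position is argued against as the main source by the reference on the same arrays: the SD of the Cy5 difference was 0.0856 of the Cy3 SD in untreated and 0.0769 of it in iron arrays. Loess is argued against by median centring in its place, under which the SD of the difference in log2 ratios was 0.79 in untreated and 0.93 in iron cultures, against 0.71 and 0.83 in the reported values. Leaving out background subtraction gave 0.72 and 0.84. The spread was thus present without that step, which argues against it as the main source. The scanner software's own values gave 1.20 and 1.40, so the size of the spread depends on the processing. A wrong sample label cannot be told apart from a real difference between cultures: grouping the arrays by replicate number called 22 genes with limma and the crossed grouping 0, against 0 for the labelled one, with 487, 29 and 172 at an unadjusted p under 0.05 and 135, 3 and 24 at least 2-fold apart, and no named iron gene is at hand to check the labels. The series' design text names untreated replicate 2 under both conditions. Exchanging its label with that of iron replicate 1 gives the grouping by replicate number. That array's own labels put it among the untreated. Differences between cultures in growth, harvest, RNA extraction or Cy3 labelling were not tested.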
